A study of Mus musculus with 12 samples.

How the data were processed

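Bulk RNA-seq libraries of mouse embryonic day 12.5 ventricles, 6 from control and 6 from Wnt gain-of-function hearts, were analysed from the authors' gene-level tables. RNA was extracted with Trizol and libraries followed Illumina protocols, per the labels' protocols. The submitters' processing notes name Subread, its counting program featureCounts, and edgeR. The genome build, the annotation release, tool versions, strand setting and the aligner's options are not given in the sources used here. Genes that overlap, or that share reads with near-identical copies such as the haemoglobin genes or Gapdh, are therefore uncertain.

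The deposited count table gives whole-number read counts per Ensembl gene and library, per the file headers. It has 41422 rows for 40800 gene IDs. The 402 IDs on several rows carry identical counts on each, so 622 repeated rows were left out. GC percent of each gene stands in the deposited table as an annotation column, per the file headers, and was not used here. The authors' deposited comparison table gives log2 fold changes, a log-odds score, p-values, adjusted p-values and log2 CPM per library, with columns named as limma writes them, per the file headers. In that deposited table, 100% of the log2 values lay within 0.1% of log2 of count plus 0.5 divided by 1 constant per library. The deposited fold column of that table equals 2 to the power of the log2 fold change for positive values, but 1 divided by the size of the log2 fold change for negative ones, each for 100% of rows within 1%, so it was not used. All sample columns were matched to samples by title.

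Samples were grouped by the genotype in the labels, and replicate numbers were taken from the titles. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10, which left 14774. Libraries were scaled by the trimmed mean of M values (TMM), and the groups were compared with the robust quasi-likelihood test (glmQLFit and glmQLFTest) with group as the only term. P-values were adjusted by Benjamini-Hochberg and called under 0.05. Log2 fold changes are Wnt gain of function against control, and their SE was derived from the F statistic. CPM values use TMM-scaled library sizes.

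Before the data were examined, 35 gene lists were fixed with 632 gene symbols in all, of which 6 were not found in the count table. Lists were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the 35 lists, and again with an estimated correlation, with camera on ranks and with fry. The genes named in the text follow a rule fixed at the same time. It takes the 8 higher and 8 lower called genes with the largest fold change among those with a mean log2 CPM of at least 0, no overlap between groups and an established symbol. It adds Ctnnb1, Axin2, Lef1 and Gja1, the sex genes, and the members with the lowest p of each list, 4 for the Wnt targets, both channel lists, the junction, atrioventricular canal and chamber lists and 2 for the others. A gene that this rule takes is not reported here. Tcf7, Dkk3, Kcne1, Pln, Actn2, Myom2, Eln in the comparison with the authors' table, Dkk4, Sp5 and further genes in the closing section were named after their values were seen.

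Alternatives were the replicate number as a block, size factors of DESeq2 in edgeR, library size alone, upper-quartile scaling, DESeq2 1.42.0, limma-voom, no or a stricter count filter (1 CPM in 6 libraries), a threshold of 0.01, a test against a log2 fold change of 0.5, haemoglobin genes left out, a covariate of Y-linked expression, and each library left out. Chosen after seeing the data were the library sets as a block and the closest pairs summed. The sets came from average-linkage clustering, cut into 3, of correlations between the libraries' deviations from their group means. Numbers shared by a control and a Wnt gain-of-function library did not pair them, with correlations of those deviations from -0.377 to 0.463. Library pairs were compared by a chi-square per gene over genes with at least 20 counts in the pair. No pair agreed within sampling noise, for which the mean is about 1, but separate preparations of the same sample can exceed it too, so this does not show that the closest pairs are separate samples. The labels give 12 samples, which were counted as separate, and the summed pairs are the alternative.

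The test was checked on counts simulated from the real means, dispersions and library sizes of this comparison, with 14621 genes tested. It recovered 98% of genes raised by 2 and 90% of genes raised by 1 on the log2 scale, and 100% and 77.1% of those lowered by as much, and 4.41% of its calls were false. Camera called the 1 simulated list that was changed and 0 of the others. The simulated counts were drawn independently for each gene and library, without library sets, close pairs or correlation between genes. These shares therefore do not show how the tests behave on the real libraries. For the neighbour test, 14740 of 14774 tested IDs were matched to GENCODE M21 on GRCm38, which may not be the authors' build, so positions were used only for chromosomes and distances between genes.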

Results

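Gene expression was measured by bulk RNA sequencing of heart ventricles from mouse embryos at embryonic day 12.5. Of the 12 libraries, 6 came from control ventricles and 6 from ventricles with Wnt gain of function, that is, raised activity of the Wnt signalling pathway. The labels do not say which engineered allele or Cre driver was used, nor whether a library holds 1 embryo or several. The deposited counts summed to 10130088 to 17526325 per control library and to 12127026 to 17184662 per Wnt gain-of-function library, each gene counted once. Of 40800 genes in the count table, 27743 had at least 1 count and 14774 passed the low-count filter and were tested. The design asks which ventricular genes differ between the groups, and the title of the series places this question in the setting of arrhythmia. The p-values measure the spread between these libraries, which the labels do not tie to separate animals.

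Notum, Axin2 and Rnf43, which encode feedback inhibitors of canonical Wnt signalling, were higher in the Wnt gain-of-function ventricles. Notum (ENSMUSG00000042988), a secreted enzyme that inactivates Wnt ligands, rose from 0.516 ± 0.304 to 15.1 ± 7.82 CPM (counts scaled by library size, mean ± SD, n = 6 per group), a log2 fold change of 4.84 ± 0.649 (SE). Axin2 (ENSMUSG00000000142), a scaffold of the beta-catenin destruction complex and a standard readout of the pathway, rose from 2.97 ± 1.09 to 18.3 ± 8.18 CPM, a log2 fold change of 2.62 ± 0.404. Rnf43, which removes Wnt receptors from the cell surface, rose from 0.58 ± 0.116 to 2.54 ± 1.04 CPM. Their adjusted p-values in edgeR's quasi-likelihood test were 0.0095 for Notum, 0.0145 for Axin2 and 0.0095 for Rnf43.

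Of the 14 Wnt target genes measured, 3 rose, 0 fell and 11 did not pass the edgeR test over all genes, while 10 were higher when p-values were adjusted over the list alone. DESeq2 called 9, limma-voom 0, and edgeR called 8 of 16 tested without Wnt gain-of-function replicate 5, Nkd1 among them (adjusted p = 0.000215). When the closest library pairs were summed, edgeR called 0 higher genes. The replicate number as a block kept Notum (edgeR adjusted p = 0.00119) and Rnf43 (0.00769) but not Axin2 (0.125). The list median was a log2 fold change of 1.33, and 12 of its 14 members lay above 0. Among those that missed the threshold over all genes, Nkd1 had a log2 fold change of 1.99 (adjusted p = 0.0573), Tcf7 of 0.87 and Lef1, a transcription factor that acts with beta-catenin, of 1.38 ± 0.413 (adjusted p = 0.335). The list as a whole rose in limma's camera test (adjusted p = 3.71e-14), a call that an estimated correlation did not keep (adjusted p = 0.0858 with an estimated correlation). Of 29 ligands, receptors and secreted modulators of the pathway, the inhibitor Dkk2 rose by a log2 fold change of 3.29 ± 0.511 (edgeR adjusted p = 0.0176) and Sfrp1, another secreted antagonist, fell by 0.41 on the log2 scale (0.045). Both kept their direction, but Sfrp1 missed the threshold in 15 of 25 alternatives and Dkk2 in 8. The 14 genes of the beta-catenin complex had 0 calls by edgeR or DESeq2, 0 members at an unadjusted p under 0.05, and a median log2 fold change of 0.02. Camera called neither list (adjusted p = 0.377 and 0.588). The mixed test of fry, which asks for change in either direction, called the first of them (adjusted p = 0.0283) but not the second (0.881). A few strong members can be enough for a call of this mixed test, so it does not show a change of the list as a whole. Ctnnb1 itself, which encodes beta-catenin, was at 278.6 ± 15.5 CPM in control and 288.2 ± 26.9 CPM in Wnt gain-of-function libraries (adjusted p = 0.999), although gene-level counts cannot show a change of single exons.

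**Figure D1:**
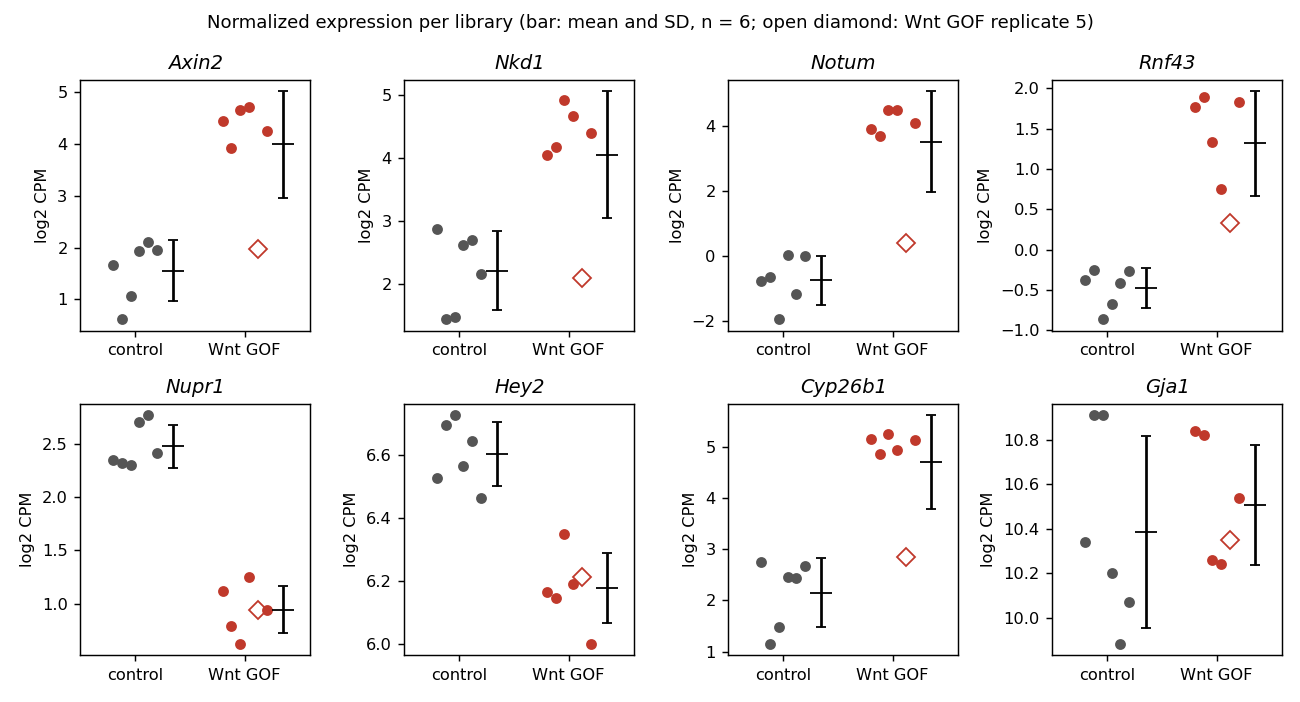
Normalized log2 CPM of 8 genes in each library, control in grey and Wnt gain of function in red, with the mean and SD of the 6 libraries of a group beside the points. The open diamond is Wnt gain-of-function replicate 5, which lies at 1.97 for Axin2 where the other 5 libraries of its group reach 3.91 to 4.71, and at 0.94 for Nupr1, among the other libraries of its group.

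Over all tested genes, 64 were higher and 10 lower at an adjusted p under 0.05 in edgeR, which is 0.501% of those tested. At an unadjusted p under 0.05 there were 931 of the 14774 tested genes. The median log2 fold change was 1.68 among the higher genes and -0.81 among the lower ones, and 48 of the higher and 5 of the lower genes changed more than 2-fold. The groups did not overlap in 22 of the 64 higher and in 8 of the 10 lower genes. Over all tested genes 0.46% did not overlap, where chance alone gives 0.216%. With 3 sets of libraries that cut across the groups as a block, chosen after seeing the data, edgeR called 195 higher and 100 lower genes. The share of higher genes was then 66.1%. The sets were found by clustering these same libraries. P-values with this block, here and below, can therefore be too small and its counts too large. The counts without the block also rest strongly on single libraries. Without Wnt gain-of-function replicate 5, which lay near the control libraries at the Wnt targets, they were 149 and 28, whereas without replicate 1, 2 or 4 of that group the higher genes numbered 35, 34 and 37. When each of the 3 closest library pairs was summed into 1 sample, 0 higher genes and 1 lower gene, Nupr1, remained in edgeR, with 600 genes at an unadjusted p under 0.05.

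Among the higher genes with no overlap between groups, several outside the Wnt lists had large changes. Cyp26b1, which degrades retinoic acid, rose from 4.67 ± 1.86 to 29.1 ± 11.3 CPM (n = 6), a log2 fold change of 2.64. Scn4b, an auxiliary subunit of voltage-gated sodium channels, had a log2 fold change of 2.33, Skap1, an adaptor protein of T cells, of 2.07, the sulfate transporter Slc13a4 of 1.80, Brinp2 of 1.68 and Dach2 of 1.66. The edgeR adjusted p was 0.0145 for Cyp26b1, Scn4b and Slc13a4, 0.0149 for Dach2, 0.0216 for Skap1 and 0.0404 for Brinp2. Scn4b, Skap1, Brinp2 and Dach2 were low, at 0.75, 0.715, 0.646 and 1.02 CPM in control libraries. They reached 3.84, 2.92, 2.12 and 3.18 CPM in Wnt gain-of-function libraries. Brinp2 barely cleared overlap, with 0.814 CPM in Wnt gain-of-function replicate 5 against 0.804 in control 3, and missed the threshold in 14 of 24 alternatives.

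The lower genes were led in size by Rgs5, a pericyte and vascular smooth muscle gene, which fell from 78.8 ± 29.7 to 13.5 ± 9.17 CPM (n = 6), a log2 fold change of -2.54 ± 0.461 (edgeR adjusted p = 0.0404). It kept its direction but missed the threshold in 15 of 25 alternatives, with an adjusted p of up to 0.579. Nupr1 (ENSMUSG00000030717), a stress-induced nuclear protein, had the smallest adjusted p of all genes, 0.000693, and fell from 5.46 ± 0.822 to 1.80 ± 0.298 CPM, lower in 6 of 6 libraries than in any control library. Clca3a2 had a log2 fold change of -1.93, the procollagen-processing enzymes Adamts2 and Adamts3 of -1.13 and -0.61, the matrix protein Smoc2 of -1.01 and Fam213b of -0.60. Adamts3 missed the threshold in 12 of 25 alternatives, Adamts2 in 9 and Clca3a2 in 8. Hey2, a transcriptional repressor of the ventricular compact myocardium, fell from 97.4 ± 6.9 to 72.4 ± 5.64 CPM, a small but non-overlapping change of -0.43 ± 0.0716 on the log2 scale (edgeR adjusted p = 0.0145).

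Few genes of cardiac conduction and excitability passed the gene-wise test. Of 15 sodium and calcium channel genes, Scn4b alone passed in edgeR, 5 had an unadjusted p under 0.05 and DESeq2 called 1. Scn7a and Scn10a had log2 fold changes of -0.48 and -0.51. Of 20 potassium channel genes, 0 passed in edgeR, 6 had an unadjusted p under 0.05 and DESeq2 called 1. In both channel lists the share at an unadjusted p under 0.05 was larger than the 931 of 14774 over all tested genes. With the library sets as a block, edgeR called 3 of the potassium channel genes. Kcne1 was lower (log2 fold change -0.5485, adjusted p = 0.000103, against 0.604 in edgeR without the block). Kcnd2 (0.00933) and Kcnd3 (0.0128) were higher. Without the block, Kcnd3 and Kcnd2, which encode channels of the transient outward current, had log2 fold changes of 0.82 (adjusted p = 0.0627) and 0.66 (adjusted p = 0.266), and Kcne3 and Kcna5 of -0.41 and -0.50. Adjusted over the list alone, 2 potassium channel genes were higher and 2 lower. Of 17 gap junction and intercalated disc genes, 0 passed in edgeR or DESeq2 and 1 had an unadjusted p under 0.05. Gja1 (ENSMUSG00000050953), which encodes connexin 43, was at 1388 ± 429.6 and 1477 ± 281.5 CPM (log2 fold change 0.09 ± 0.184, edgeR adjusted p = 0.999), and Gja5, Dsg2, Dsc2 and Cdh2 had log2 fold changes of -0.35, -0.22, -0.29 and -0.21. Of 19 calcium-handling genes, 0 passed in edgeR or DESeq2 and 4 had an unadjusted p under 0.05, among them Casq1 at 0.38 and Atp2a2, the sarcoplasmic reticulum calcium pump, at -0.18. The block called 1 of them, Pln, lower (adjusted p = 0.0355). None of these 4 lists was called by camera (adjusted p from 0.128 to 0.506). The mixed test of fry, which asks for change in either direction, called the sodium and calcium (adjusted p = 0.00505) and the potassium channel list (0.0163), but not the junction (0.646) or calcium-handling list (0.177). It called 10 of all 35 lists. Over the 26 lists with 0 calls in edgeR, DESeq2 called 8 of 439 members and limma-voom, which called 6 genes in all, 0. With the library sets as a block edgeR called 21 of these members, in 13 of the lists.

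**Figure D2:**
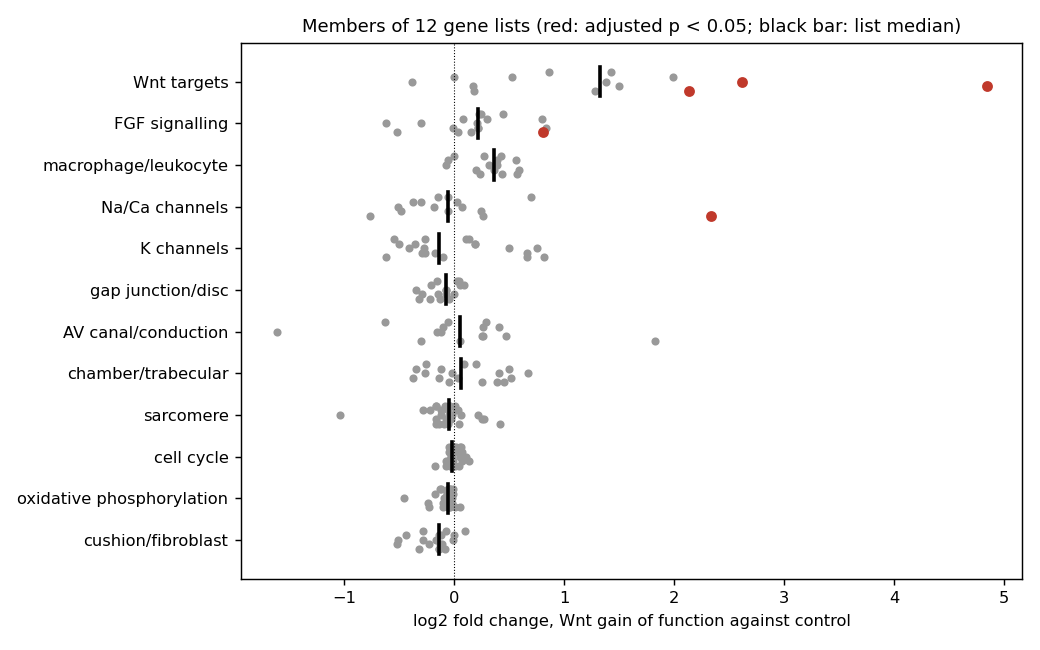
Log2 fold change of each measured member of 12 gene lists, Wnt gain of function against control, with called genes in red, other genes in grey and a black bar at the list median. The Wnt targets have a median of 1.33 with 3 called genes, while the lists of channels, junctions, sarcomere and cell cycle have medians between -0.14 and -0.02.

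Few genes of the cardiac compartments passed the gene-wise test. Of 15 genes of the atrioventricular canal and pacemaker programme, 0 passed in edgeR, 4 had an unadjusted p under 0.05 and DESeq2 called 1. The transcription factor Msx2 had a log2 fold change of 1.82 ± 0.437 (adjusted p = 0.133), Tbx3 of 0.41, Cpne5 of 0.48 and Isl1 of -1.61 ± 0.621. Of 18 chamber and trabecular genes, 0 passed in edgeR, 8 had an unadjusted p under 0.05 and DESeq2 called 3, and 4 were higher when adjusted over the list alone. The share at an unadjusted p under 0.05 was larger than the 931 of 14774 over all tested genes. Nppa, the atrial natriuretic peptide gene, was at 815 ± 127.7 and 1170 ± 187 CPM (adjusted p = 0.0842, n = 6), and Nppb, Slit2 and Nrg1 had log2 fold changes of 0.50, 0.39 and 0.67. Without Wnt gain-of-function replicate 5, edgeR called Nppa (adjusted p = 0.0132), Nppb (0.026), Slit2 (0.0296), Msx2 (0.00229), Kcnd2 (0.00809), Kcnd3 (0.0315) and Csrp3 (0.0015) as higher and Isl1 (0.028), Scn7a (0.0439) and Dkk3 (0.0481), of the atrial and Wnt component lists, as lower. Of 30 sarcomere genes 0 passed in edgeR or DESeq2 and 2 had an unadjusted p under 0.05, Csrp3 with a log2 fold change of 0.42 and Myh6 with 0.26. With the library sets as a block, edgeR called Tbx3 (0.04), Cpne5 (0.0407), Nppa (0.0123), Slit2 (0.00269) and Nrg1 (0.0242) as higher and the sarcomere genes Actn2 (0.0464) and Myom2 (0.0121) as lower. Hey2 was the only edgeR call among 23 cardiac transcription factors, where Tbx5 had a log2 fold change of 0.25. The 9 second heart field and outflow genes and the 12 atrial genes had 0 calls in edgeR or DESeq2, with 1 and 2 members at an unadjusted p under 0.05. None of these 6 lists was called by camera (adjusted p from 0.145 to 0.767), while the mixed test of fry called the chamber list (adjusted p = 0.0156), and the outflow list had a median of 0.12 but a mean of -0.15, with Fgf10 at 0.80.

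Among other signalling groups, the fibroblast growth factor list rose in camera (adjusted p = 0.00806; adjusted p = 0.234 with an estimated correlation). Of its 17 measured members 13 lay above 0, Etv5, a transcription factor induced by this pathway, rose by a log2 fold change of 0.81 ± 0.143 (edgeR adjusted p = 0.0176), and Etv4 was at 0.84 (adjusted p = 0.237). EdgeR called Etv4 higher with the library sets as a block (adjusted p = 0.0284). Of 24 genes of BMP and TGF-beta signalling 0 passed in edgeR, 5 had an unadjusted p under 0.05 and DESeq2 called 2. Inhba was at -0.72 (adjusted p = 0.0714), and 3 members were higher and 1 lower when adjusted over the list alone. Inhba passed in 7 of 25 alternatives. It was called by DESeq2 (adjusted p = 0.00386) and by edgeR without Wnt gain-of-function replicate 5 (0.0217). EdgeR also called it with the library sets (0.0285) or the replicate number (0.0237) as a block. Hey2 was also the only edgeR call among 16 Notch genes, where Hey1 was at -0.52 (edgeR adjusted p = 0.186), called by DESeq2 (0.0431) and with the library sets as a block (0.032). Neither list was called by camera (adjusted p = 0.177 and 0.128), while the mixed test of fry called the Notch list (0.0283) but not the other (0.23).

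Proliferation genes were not called as a group, with 0 of 30 replication and mitosis genes called by edgeR or DESeq2, 0 at an unadjusted p under 0.05 and a median log2 fold change of -0.02 (Kif11 at -0.18, Cdc6 at 0.14). Ccnd2, a D-type cyclin, was the only edgeR call among 17 cell cycle regulators and rose from 675.8 ± 59.7 to 964.7 ± 134.7 CPM, a log2 fold change of 0.51 ± 0.0943 (edgeR adjusted p = 0.0206). Pmaip1, which encodes the pro-apoptotic protein Noxa, was the only edgeR call among 15 p53 and apoptosis genes, with a log2 fold change of 2.44 ± 0.412 (adjusted p = 0.022). It kept its direction but missed the threshold in 12 of 25 alternatives, with an adjusted p of up to 0.479. Cdkn1a, a member of both lists, was at 0.62 (edgeR adjusted p = 0.211), called by DESeq2 (0.0493) and by edgeR without Wnt gain-of-function replicate 5 (0.0065). None of the 3 lists was called by camera (adjusted p from 0.377 to 0.788). The mixed test of fry called the cell cycle regulators (adjusted p = 0.0475) and the p53 and apoptosis list (0.00505), but not the replication and mitosis list (0.881). The list of 31 nuclear-encoded respiratory chain genes was lower in camera (adjusted p = 0.0163; adjusted p = 0.785 with an estimated correlation) with 29 of 31 members below 0, but its median was only -0.05. It had 0 calls by edgeR or DESeq2 and 3 members at an unadjusted p under 0.05, among them Cox7a1 at -0.23 and Cycs at -0.24. Glycolysis and hypoxia genes (23 measured, Gapdh at 0.58 and Pdk1 at -0.21), fatty acid oxidation genes (20, Ucp2 at 0.29 and Ppargc1b at -0.17) and extracellular matrix genes (31, Eln at -1.73 and Col1a2 at -0.32) had 0 calls by edgeR, with 1, 0 and 3 members at an unadjusted p under 0.05. DESeq2 called 1 of them, Eln (adjusted p = 0.000271), and camera called none of the 3 lists (adjusted p of 0.341, 0.377 and 0.588). The library sets as a block changed this in edgeR for the glycolysis and matrix lists. They gave Gapdh as higher (adjusted p = 0.00217), Col1a2 as lower (0.0143), and 1 glycolysis and hypoxia gene and 1 respiratory chain gene as lower.

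Markers of macrophages and leukocytes were higher as a group (camera adjusted p = 3.57e-06; adjusted p = 0.488 with an estimated correlation). Of 15 measured members 12 lay above 0 with a median log2 fold change of 0.37, 7 had an unadjusted p under 0.05, and 0 passed the test over all genes in edgeR or DESeq2. Aif1 and Tyrobp had log2 fold changes of 0.58 and 0.59 (adjusted p = 0.505 and 0.542). Cushion mesenchyme and fibroblast markers were lower in camera (adjusted p = 0.024; adjusted p = 0.72 with an estimated correlation), with 17 of 19 members below 0, a median of -0.14, 0 calls in edgeR or DESeq2, 1 member at an unadjusted p under 0.05, and Col1a1 at -0.52. Rgs5 was the only edgeR call among 11 smooth muscle and pericyte genes, where Notch3 was at -0.28. The mixed test of fry called this list (adjusted p = 0.000431), for which a single strong gene can be enough. The directional test of fry did not call it (adjusted p = 0.43). Endocardial and endothelial (20 genes, Npr3 at 0.44, Tek at 0.16), epicardial (12 genes, Sema3d at 0.15, Krt19 at 0.17), erythroid (16 genes, Hbb-bt at -0.38, Hbb-bs at -0.37) and neural crest and neuronal markers (9 genes, Stmn2 at -1.22) had 0 calls in edgeR or DESeq2, with 1, 0, 0 and 2 members at an unadjusted p under 0.05. With the library sets as a block, edgeR called Npr3 higher (0.0257), and Stmn2 (0.002) and Col1a2 of the cushion list (0.0143) lower. No call in edgeR or DESeq2 was made either among markers of liver, foregut and lung (6 genes, Apoa2 at 0.65, Ahsg at 0.52), of skeletal muscle (4 genes, Myh8 at 1.02, Actn3 at 0.23), of dissection stress (13 genes, Dusp1 at -0.26, Zfp36 at -0.16) and of mitochondrially encoded transcripts (7 genes, mt-Nd6 at -0.23, mt-Nd4 at -0.19), with 0, 0, 0 and 1 members at an unadjusted p under 0.05. The library-set block gave Myh8 as higher (edgeR adjusted p = 0.0451). Camera called none of these other lists of cell types and quality (adjusted p of 0.0647 or more). With the library sets as a block it called the mitochondrially encoded list lower (adjusted p = 0.000113; adjusted p = 0.395 with an estimated correlation), with 7 of 7 members below 0.

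The libraries differed in ways the groups do not explain. Clustering of the deviations from the group means, cut into 3, gave sets of 4 libraries, each with 2 control and 2 Wnt gain-of-function libraries. The first set held control replicates 2 and 3 with Wnt gain-of-function replicates 1 and 2. The second held control 4 and 5 with Wnt gain-of-function 3 and 4, and the third control 1 and 6 with Wnt gain-of-function 5 and 6. The third set was loose, with correlations of the deviations between its libraries from -0.0754 to 0.134. They were 0.463 to 0.605 in the first set and 0.362 to 0.492 in the second. Wnt gain-of-function replicate 5 correlated more with control 4 of the second set (0.169) than with any library of its own set. Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d, Uty) were high in every library of the first set and near the floor in every library of the second, where Xist was at 8.52 to 8.77 log2 CPM. None of these 5 sex genes was called between the groups by edgeR or DESeq2, 0 had an unadjusted p under 0.05, and camera did not call their list (adjusted p = 0.61). The share of counts from haemoglobin genes ranged from 0.948% to 7.37% in control and from 1.19% to 8.73% in Wnt gain-of-function libraries. Within the sets, with 2 libraries against 2, all 64 higher genes were above 0 in the first and second set, as were all 60 that could be tested in the third, and the 10 lower genes were below 0 in each. These genes were called from the same 12 libraries, so their direction within the sets is no independent evidence. Their median log2 fold changes were 2.14, 1.48 and 1.04 for the higher and -0.73, -0.87 and -0.54 for the lower genes. Axin2 had log2 fold changes of 3.36, 2.71 and 1.74 in the 3 sets and Nupr1 of -1.44, -1.80 and -1.51. In the third set Axin2 was not called (edgeR adjusted p = 1), with 18.9 CPM in Wnt gain-of-function replicate 6 and 3.77 CPM in replicate 5 against 3.01 and 3.71 CPM in the control libraries, and edgeR called 1 higher and 1 lower gene there. In the first set edgeR called 1298 higher and 1227 lower genes, and in the second 385 and 480. These 2 sets hold the 3 closest library pairs, which may not be separate samples, so their p-values may not measure the spread between animals. At the preset correlation, camera gave the Wnt targets adjusted p-values of 4.85e-10, 2.02e-11 and 0.0208 and the macrophage markers 0.00148, 0.00306 and 0.0287 in the 3 sets. It gave the cushion list 0.901, 0.641 and 1.45e-06. None of these calls was kept with an estimated correlation (adjusted p of 0.39 or more within the sets), nor were those of all 12 libraries. Camera called the fibroblast growth factor and respiratory chain lists in none of the sets (adjusted p of 0.0942 or more).

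**Figure D3:**
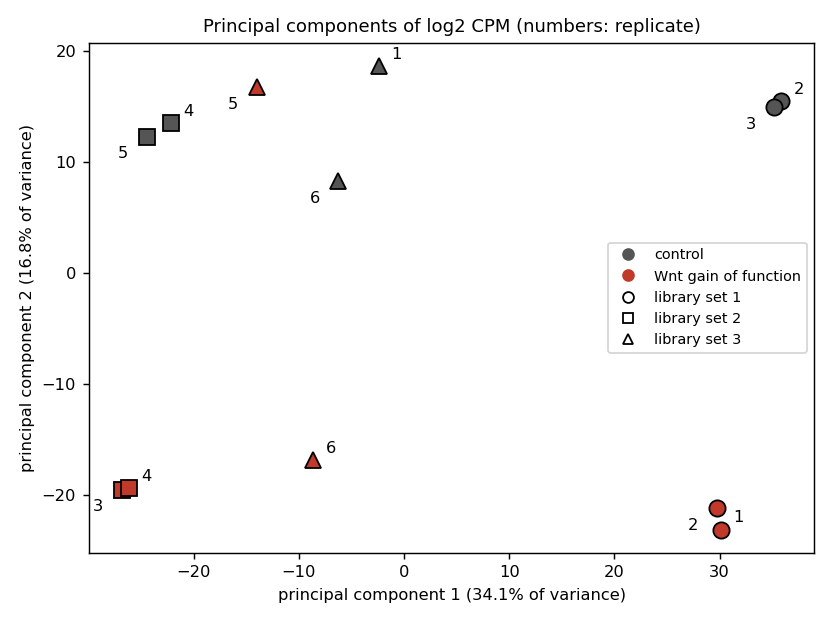
Libraries on the first 2 principal components of log2 CPM, which hold 34.1% and 16.8% of the variance, with control in grey, Wnt gain of function in red, the replicate number beside each point and the library set as its shape. The first component follows the library sets, and on the second 5 Wnt gain-of-function libraries lie below 0 while replicate 5 lies at 16.7 among the control libraries.

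The authors' deposited table of their own comparison covered 27743 genes, all those with at least 1 count, and held 28 higher and 8 lower genes at an adjusted p under 0.05. Nupr1 also had the smallest p there (log2 fold change -1.58, adjusted p = 0.00221 in the authors' deposited table). Axin2 and Notum had adjusted p-values of 0.0756 and 0.179 in the authors' deposited table, while Rnf43 was called there (0.0453). Across the 14774 genes tested in edgeR, log2 fold changes of both sources had a Spearman correlation of 0.972 across genes, which are not independent replicates, and the same sign in 95.5% of genes. Of the 36 genes called in the authors' deposited table, 24 were also called in edgeR, 11 fell below the low-count filter, among them the Wnt targets Dkk4 and Sp5, and 1, Eln, was tested and not called (edgeR adjusted p = 0.076), though edgeR called it without Wnt gain-of-function replicate 5 (8.65e-05) and with the replicate number as a block (0.00758).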

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

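The tests of Wnt gain-of-function replicate 5 in this part were chosen after its values were seen. Of 92 sets of 6 values examined, 11 held a library far from the other 5, where chance alone gives about 1 in 20, and 10 of the 11 concerned this replicate. At Wnt targets and other higher genes it lay far below the others. Its log2 CPM was 0.414 for Notum against 3.71 to 4.49, 1.97 for Axin2 against 3.91 to 4.71, 2.1 for Nkd1 against 4.05 to 4.91, 1.1 for Msx2 against 3.01 to 3.89, 2.84 for Cyp26b1 against 4.86 to 5.24, 2.55 for Slc13a4 against 3.6 to 4.23 and 3.04 for Kcnd2 against 4 to 4.31. Over the Wnt target list its mean was 2.82 against 3.86 to 4.16. It lay above the others for Isl1, at 3.55 against 0.764 to 1.59, and for Scn7a, at 2.67 against 1.64 to 1.99. The remaining value was Adamts2 in Wnt gain-of-function replicate 6, at 1.28 against 2.14 to 2.65.

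For replicate 5, genes were called without it and without 1 control library, in 6 fits that left out each control library in turn. It lay beyond the 5 other control libraries, on the Wnt gain-of-function side, at 22% to 30% of these genes, and the left-out control libraries did so at 18.7% to 28.9%. Of the 17 or 18 further genes called in a fit that the count filter over all 12 libraries left out, it did so at 2 to 4 and the left-out control libraries at 2 to 5. That filter asks for expression in 6 libraries, so genes silent in control libraries were left out only where replicate 5 was low too. These further genes thus cannot decide the question. By the shares over the other genes, a control library under a wrong label cannot be told apart from a weakly affected one. A swap with a control library is argued against, since the highest median position of a left-out control library was 0.164, on a scale from 0 at the other control libraries to 1 at the other Wnt gain-of-function libraries. A fixed share of control tissue in this library cannot be told apart either. At 5 to 11 called genes it lay at a position of 0.75 or above, against 3 to 11 of the left-out control library shifted by the median position of replicate 5, more in 3 of the 6 fits and fewer in 2. Lower activation of the pathway in these hearts stays open and was not tested.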

How the results depend on the processing

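The library sets, the summed pairs and their combinations with a left-out library were chosen after seeing the data. The sets were found in these same libraries, so counts with them as a block can be too large. Against 64 higher and 10 lower genes, the counts were 97 higher without a count filter, 110 and 19 with Y-linked expression as a covariate, 168 and 25 with DESeq2, 3 and 3 with limma-voom, 13 and 1 against a log2 fold change of 0.5, and 8 and 2 at an adjusted p under 0.01. With the library sets as a block they were 195 and 100, and 412 and 308 when Wnt gain-of-function replicate 5 was also left out. Summing the 3 closest pairs gave 0 and 1, and 103 and 10 without replicate 5, with 57 of the 64 higher and 5 of the 10 lower genes kept. No filter without replicate 5 gave 194 and 34. Leaving out 1 library gave 34 to 149 higher and 4 to 28 lower genes. Lower genes numbered 6 without control replicate 3, 5 without Wnt gain-of-function replicate 1, 2 or 4, 4 without replicate 3 and 28 without replicate 5, where all 74 main calls were kept. The shift with the scaling was small, with 63 to 65 higher and 10 lower genes. The replicate block gave 47 and 8, in samples that share only a number, and 2 of 6 control libraries correlated best with their own number.

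Of the 5 lists called by camera, 0 were called with an estimated correlation and 1, the Wnt targets, by fry, and 3 to 7 when 1 library was left out. The mitochondrially encoded list was newly called with the library sets (adjusted p = 0.000113) or the replicate number (0.0234) as a block, and under neither with an estimated correlation. The authors' table held 3 calls at an adjusted p under 0.01, and its Spearman correlation with edgeR was 0.974 over genes with a mean log2 CPM of at least 0. Of 91 named genes under 24 or 25 alternatives each, no called gene changed its direction. The 22 called ones passed in 412 and missed the threshold in 137 fits, and the others passed in 53 and did not in 1668. Nupr1 passed in all 25. Except where fewer samples, fewer genes or a stricter threshold set the count by construction, the cause was not tested. With totals of 10130088 to 17526325, a gene at 1 CPM rests on few counts in each library.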

Other observations

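Genes in the next 2 paragraphs were chosen after their values were seen, and all tests of this part except the splits of the 12 libraries were too. Several genes that were nearly silent in control ventricles were left out by the count filter, which asks for expression in 6 libraries, and were found by leaving out Wnt gain-of-function replicate 5. Chodl, a membrane lectin, was at 0.362 CPM in control libraries, 32.3 ± 5.14 CPM in the other 5 Wnt gain-of-function libraries and 0.222 CPM in replicate 5 (edgeR adjusted p = 1.74e-10 without it). Sostdc1, an antagonist of BMP and Wnt ligands, was at 0.176 and 21.7 ± 7.59 CPM, with 0.592 CPM in replicate 5. Mixl1, a homeobox gene of the primitive streak, was at 0.16 and 6.86 ± 1.93 CPM, and Myot, a Z-disc protein, at 0.316 and 7.46 ± 1.87 CPM. The Wnt targets Sp5 and Dkk4 reached 2.84 ± 0.559 and 1.06 ± 0.199 CPM, from 0.115 and 0.0584, with 0.518 and 0.37 CPM in replicate 5, which are 7 and 5 counts against at most 4 and 1 in a control library. In all, 19 genes outside the main filter were called this way, 1 of them, Map3k7cl, as lower. Since the filter over all libraries had left these genes out, the low values of the higher ones in replicate 5 follow from that choice.

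Further called genes belonged to no fixed list. Hspa2, a heat shock protein of the HSP70 family, had a log2 fold change of 1.08 (edgeR adjusted p = 0.00282), the cadherin Cdh6 of 1.28 and Angpt1, a ligand of the endothelial receptor Tek, of 0.66. Runx1 and Runx2 had log2 fold changes of 1.76 and 1.99, the relaxin receptor Rxfp1 of 2.50, and Nos1ap, an adaptor of neuronal nitric oxide synthase, of 0.70 (adjusted p = 0.022). Dpp6, a partner of Kcnd channels, had a log2 fold change of 3.91, and the glutamate receptor genes Grin3a and Grik1 of 2.96 and 3.55. Grin3a and Grik1 missed the edgeR threshold with the library sets as a block (adjusted p = 0.0526 and 0.0508).

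Other splits of the 12 libraries into 6 and 6 were drawn 100 times, the real one included. The 74 genes of the real split were reached by 2 splits with the real one, but the highest other split called 1725. That split set control 1, 4, 5 and 6 and Wnt gain-of-function 3 and 4 against the rest, which parts the first from the second library set and points to a structure of the samples. Of the 20 splits drawn that balanced the sets, only the real one reached 74. The sets were found after the real group means were taken out. Splits that balance the sets or run within them therefore favour the real one. Of 100 splits within the sets with the sets as a block, 3, the real one included, reached its 295 genes, and the highest other, 553, exchanged Wnt gain-of-function replicate 5 with control 6, the next, 300, with control 1. The number of called lists, 5, was reached by 57 of 100 splits (highest other 19). For single lists, a camera p as small came from 1 split for the Wnt targets (smallest other 6.55e-11), 1 for fibroblast growth factor signalling (0.00255), 4 for macrophage markers (1.13e-09), 41 for the respiratory chain (2.85e-13) and 32 for cushion and fibroblast markers (1.99e-08).

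These splits favour the real one, since the 3 closest library pairs each lie within a group and most random splits break them. In the splits within the sets, the 3 with the most genes all keep these pairs together. All 46 splits that keep each pair on the same side were therefore run too. Of these, 10, or 21.7%, called 74 genes or more (highest other 2796), so chance is not excluded for the number of genes once the pairs are kept. Of the 12 that also balance the sets only the real one did, and the next, with 71, exchanged replicate 5 with control 6. Balance over sets that were found after the real group means were taken out favours the real split, so this does not exclude chance. A camera p as small came from 2 of 46 splits for the Wnt targets (smallest other 3.46e-20, with replicate 5 and control 1 exchanged), 3 for fibroblast growth factor signalling (0.000186), 4 for macrophage markers (2.61e-08), 20 for the respiratory chain (2.32e-13) and 11 for cushion and fibroblast markers (4.62e-07). Among the 5 lists, only for the Wnt targets did under 5% of splits of both kinds give a p as small, with 4.35% of the 46. Since 5 lists were tested without correction and the 46 splits were chosen after seeing the data, chance is not excluded for this list. It is not excluded for the number of lists either.

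For the 3 library sets, the sex of the embryos as the whole cause is argued against. The control libraries of the third set carry Y-linked transcripts, yet lie at 0.326 on a scale from 0 at the second set, without such transcripts, to 1 at the first, with them. The haemoglobin share was 0.948% to 1.26% in the first set and 3.69% to 7.37% in the second. In the third it ran from 1.454% to 8.731%, yet its libraries spread over only 0.133 of that scale. The place of Wnt gain-of-function replicate 5 depends on the genes used, so different amounts of blood cannot be told apart from other causes. The sets were defined on all tested genes, and all 12 libraries kept their set with the 3000 most variable ones. With the 1000 most variable ones, replicate 5 alone moved and joined the second set, so only the 4 libraries of the first set kept exactly the same mates. Results that use the sets rest on that choice of genes. A difference in stage, dissection or library batch stays open and the labels give none of them. The closest pairs, Wnt gain-of-function 3 and 4, Wnt gain-of-function 1 and 2, and control 2 and 3, had a mean chi-square per gene of 3.07, 3.10 and 3.32, against 12.8 to 93.1 in other pairs within a group. Whether they share embryos is not stated in the labels. Wnt gain-of-function replicate 6 had both Xist (7.85 log2 CPM) and Y-linked transcripts (mean 5.07 log2 CPM), where other libraries had one or the other.

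Of 177 genes called with or without replicate 5, 158 passed the count filter over all 12 libraries. At 14 of these, replicate 5 lay beyond all control libraries and at or past the nearest of the other libraries of its group, among them Nupr1, Hey2, Skap1, Clca3a2, Gnb1 and Fam213b. One hypothesis is that such genes may lie near the engineered loci and differ by linked alleles. Gnb1 and Fam213b are neighbours on chromosome 4, 0.628 Mb apart, but this was the only pair within 5 Mb, and a share of 0.39 of 10000 random gene sets held as many. The 14 genes lie on chromosomes 1, 3, 4, 5, 6, 7, 10, 11, 13, 15, 16 and 18. Linkage to a few engineered loci thus cannot account for all 14 genes. It could still hold for some of them, since genes in the set by chance would scatter over chromosomes too. The count of pairs cannot decide this, since it was neither 0 nor above that of most random sets. For single genes such as this pair, linked alleles cannot be told apart from chance.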
